A study of Mus musculus with 14 samples.

How the data were processed

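RNA sequencing was done on cells sorted from the bone marrow of C57BL/6 mice. Per the labels, mice had received Plasmodium yoelii, a rodent malaria parasite, 6 weeks before (Plas) or PBS, and some were sampled 3 hours after CLP, an abbreviation that the labels leave unexplained. The sorted populations were HSPC (Lin- cKit+ CD34+), GMP (a gate written with Sca1-, Cd16/32+ and CD34-) and monocytes (CD45+, CD11b+, Ly6Chi, Ly6G-). The labels also state TruSeq stranded mRNA libraries from 300 ng of RNA and an average of 20 M reads. There were 14 libraries: 1 HSPC library each for PBS and Plas, and 2 libraries each of GMP PBS, GMP Plas, monocyte PBS, monocyte Plas, monocyte PBS_CLP and monocyte Plas_CLP. Replicates are numbered by their labels, and the file behind GMP_Plas replicate 2 is itself numbered 3. Whether the 2 libraries of a group came from separate animals is not given in the sources used here, so p-values measure only the spread between these samples.

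The submitters' notes name FastQC, Bowtie, DESeq2 and the build mm39 without versions, and the role of each step is not given in the sources used here. The deposited files carry the column names of MMSEQ gene-level output, and the same 22469 gene identifiers are in each. The deposited column of unique hits is a count of fragments assigned to 1 gene alone. It was read as a count per gene and was the basis of every test. The deposited expression estimate is on the natural log scale, and with the deposited effective length in bases it was used only to rebuild estimated counts for an alternative setting. Symbols were taken from the GENCODE M21 annotation by gene identifier, which gave names to 22363 identifiers and left 106 without. Because that annotation belongs to an earlier genome build than mm39, no coordinates are given.

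Total unique hits ranged from 166331 to 10403283 per library. A count of 0 allows up to 3 counts, which was 0.288 to 0.359 CPM (counts scaled to a common library total) in the 7 libraries with at least 8356267 hits and 8.95 to 18.0 CPM in the other 7. Intervals are 95% and, like these floors, cover counting error only, since the reads carry no molecular identifiers.

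Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr with a minimum count of 10 and a minimum total of 15, robust quasi-likelihood fit, two-sided quasi-likelihood F test, Benjamini-Hochberg adjustment over all genes tested, threshold 0.05). The 4 GMP libraries were fitted together (10485 genes), the 8 monocyte libraries together (5568 genes), and all 12 GMP and monocyte libraries together (11234 genes) for comparisons between cell types. Group means in CPM are on the TMM-scaled totals and values per library on the library totals. Errors of log2 fold changes are standard errors (SE) from these fits. A gene was said to rise or fall only when its adjusted p was under 0.05. A fold change against a group at 0 counts is given as a lower bound against 3 counts over the group, and one against 1 to 3 counts is given with its exact counting interval. The HSPC libraries, 1 per condition, were compared as log2 ratios with a prior count of 2 and no test.

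A total of 39 gene lists (826 genes, 824 of them matched) for blood cell types, interferon, inflammatory, metabolic, cell-cycle and stress programmes was fixed before the data were examined, as were the tests, the comparisons and the rule for naming genes. Lists with at least 3 measured genes were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Lists of the HSPC libraries were placed among the medians of 10000 random lists of the same size.

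The rule for named genes took, per comparison, the 12 largest log2 fold changes in each direction among protein-coding genes with an adjusted p under 0.05, a mean of at least 10 CPM in the higher group and no overlap between the libraries of the groups. Predicted genes and immunoglobulin or T-cell receptor segments were left out, and if nothing passed, the 5 eligible genes with the smallest p were named as not past the test. From each list up to 4 members were named, those past the test first. For the HSPC libraries the 12 largest ratios in each direction were taken among genes with at least 20 CPM in the higher library, and for the interaction and the difference between cell types the 10 genes with the smallest adjusted p. Genes of the sort gates served as checks.

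Alternatives chosen before the data were examined were RLE scaling, no filter, a filter of 50 counts in 2 libraries, estimated counts, DESeq2 1.42.0 (Wald test), limma-trend with a pseudocount of 1, a test against a 1.5-fold change, all 14 libraries in 1 fit, only the 4 libraries compared, the replicate number as a block, and each library left out in turn. Thinning to the lowest depth, removal of a length trend (lowess span 0.3), a crossed pairing of replicate numbers and camera on z-scores were added after seeing the data. Where draws are not mentioned, a value after thinning is that of the first of 20 draws. The detection of added fold changes was tested on simulated data. Tables and plots used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. No group held 3 libraries, so no other splits of the samples were counted.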

Results

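Most transcripts of the sort markers followed the gates in the GMP and monocyte libraries, but Ly6c2 and Fcgr3 were not particular to 1 population. GMP libraries held 805 to 1093 CPM of Ly6c2, and monocyte libraries held 256 to 388 CPM of Fcgr3 and 23.6 to 71.4 CPM of Kit. GMP libraries carried 256 to 308 CPM of Kit, the stem cell factor receptor, and 160 to 181 CPM of Fcgr3, which encodes CD16, while Ly6a (Sca1) stayed between 0.0961 and 0.820 CPM. Cd34 was at 151 to 208 CPM in GMP although the gate is written as CD34-. Monocyte libraries carried 620 to 1270 CPM of Ly6c2, 36.1 to 91.8 CPM of Itgam (CD11b) and few counts of the neutrophil marker Ly6g, 0.445 to 6.14 CPM in the 4 libraries of infected mice and 0 counts in the 4 others, which allows up to 18.0 CPM. They also held 168 to 320 CPM of B-cell list transcripts without Ighm and, summed over 21 mature neutrophil genes, 9070 to 17770 CPM, against 1315 to 2411 CPM in GMP and 12370 CPM in the PBS library labelled HSPC. The Plas library labelled HSPC was above the monocyte range, at 21760 CPM on its TMM-scaled total. The sum hides differences between its genes. S100a9 reached 3797 CPM in monocyte libraries, against 2800 and 5966 CPM in the PBS and Plas libraries labelled HSPC. Retnlg was at most 0.222 CPM in monocyte libraries, against 4207 and 7924 CPM. The libraries labelled HSPC had 0 counts of Kit and of Cd34, which allows at most 8.95 and 9.19 CPM, so they are described apart from the rest. Depth split the monocytes. Both PBS libraries (196073 and 211671 unique hits), both PBS_CLP libraries (188278 and 166331) and Plas_CLP replicate 1 (325923) were shallow, against 9464506 and 8995169 hits in the Plas libraries and 8356267 in Plas_CLP replicate 2. In monocytes without CLP, depth and infection thus went together, and other differences that went with depth cannot be told apart from infection. The 4 GMP libraries held 9753387 to 10403283 hits. Replicates correlated across genes at r = 0.991 in GMP PBS and in GMP Plas, 0.987 in monocyte Plas, 0.896 in monocyte PBS, 0.873 in PBS_CLP and 0.899 in Plas_CLP, where genes are not independent replicates.

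**Figure D1:**
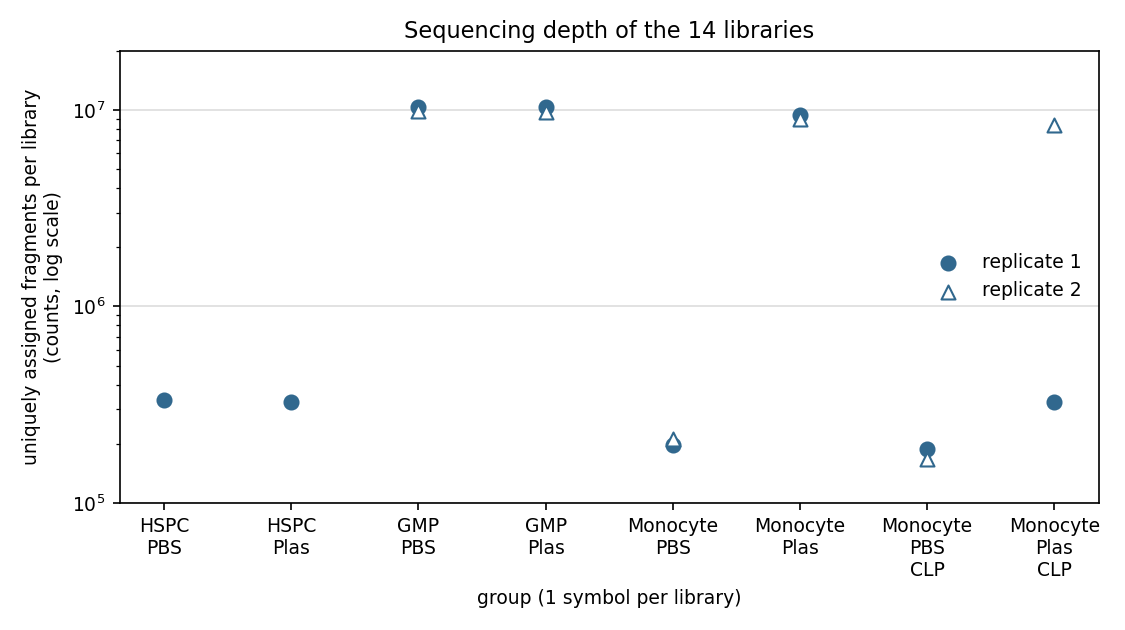
Unique fragments per library on a log axis for the 14 libraries, by group. The 7 deep libraries hold at least 8356267 fragments and the other 7 hold 166331 to 335393.

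In GMP, earlier infection raised genes of antigen presentation and of interferon-induced defence. H2-Q7, a non-classical MHC class I gene (ENSMUSG00000060550), rose by 1.96 ± 0.14 on the log2 scale (SE, n = 2 per group, adjusted p = 2.4e-10), from a mean of 15.5 to 60.2 CPM. Nlrc5, the transactivator of MHC class I genes, rose by 1.07 ± 0.14 (adjusted p = 1.0e-05, but 0.642 with estimated counts), and H2-T23, which encodes Qa-1, by 0.64 ± 0.10 (adjusted p = 0.000308, but 0.248 with all 14 libraries in 1 fit). Serpina3g, a protease inhibitor induced in activated leukocytes, rose by 1.74 ± 0.24 (adjusted p = 3.6e-05), and Gvin1, a very large interferon-inducible GTPase, by 1.65 ± 0.32 (adjusted p = 0.00197). Iigp1, a GTPase that attacks parasite vacuoles, had 33 counts in Plas against 0 in PBS and was at least 10.98-fold higher (adjusted p = 0.00419, but 0.0857 with estimated counts). H2-Q6 (1.80 ± 0.16) and Tgtp2 (1.58 ± 0.23) were also past the test. They share sequence with H2-Q7 and Tgtp1, so the split of reads within each pair is uncertain. In total 363 of 10485 genes changed (edgeR quasi-likelihood test), 158 up and 205 down, 73 of them by at least 1 on the log2 scale. Of the 50 genes named by the rule, 11 were past the test in all 14 alternatives: H2-Q7, H2-Q6, Serpina3g, Tgtp2, Fcer1a, Mcpt8, Cpa3, Lrg1, Hspa1a, Hspa1b and S100a11. The total was 74 with estimated counts, 42 with all 14 libraries in 1 fit, 155 without GMP_Plas replicate 2, 228 without GMP_PBS replicate 1 and 618 without GMP_Plas replicate 1.

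By list, 33 of the 35 measured type I interferon genes had positive changes in GMP (median 0.71). Of the 35, 10 rose and 0 fell over all genes tested (16 and 0 adjusted over the list alone), and the list moved up (camera adjusted p = 6.4e-14; adjusted p = 0.521 with an estimated correlation). Rtp4, a receptor transporter induced by interferon, rose by 3.14 ± 0.73 (adjusted p = 0.0116), a call lost without GMP_PBS replicate 2 (0.0624) or GMP_Plas replicate 2 (0.112), with DESeq2 (0.0906) and with estimated counts (0.0991). Zbp1, a sensor of Z-form nucleic acid, rose by 2.46 ± 0.54 (adjusted p = 0.00692), lost without GMP_PBS replicate 2 (0.0609) and with estimated counts (0.0857). Of 21 interferon-gamma GTPase genes, 11 rose and 0 fell (11 and 1 adjusted over the list alone; median 0.50), with camera adjusted p = 2.9e-09 and adjusted p = 0.521 with an estimated correlation. Fry, which asks whether a list's genes move 1 way on balance, called only this list of the 35 (adjusted p = 0.0447). Of 19 MHC class I genes, 9 rose and 0 fell (12 and 0 adjusted over the list alone; median 0.25; camera adjusted p = 4.3e-07; adjusted p = 0.521 with an estimated correlation). Of 9 MHC class II genes, 1 rose, H2-DMa, a peptide-loading chaperone (0.39). That list's camera adjusted p was 0.0322, and adjusted p = 0.54 with an estimated correlation; the call ended without GMP_PBS replicate 2 (0.366) or GMP_Plas replicate 1 (0.180).

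Lineage genes moved in opposite directions in GMP. Each library pools many sorted cells, so a changed mix within the gate cannot be told apart from changes within cells. The basophil and mast cell genes Fcer1a, the alpha chain of the IgE receptor (1.76 ± 0.23, adjusted p = 1.2e-05), Mcpt8, a basophil protease (1.49 ± 0.12, adjusted p = 5.6e-07), and Cpa3, mast cell carboxypeptidase (1.20 ± 0.10, adjusted p = 3.6e-09), rose, Mcpt8 from 82.1 to 231 CPM. Prss34, a basophil protease, rose from 95.1 to 280 CPM (1.56 ± 0.21, adjusted p = 0.0242), but its adjusted p was 0.160 with a gene-length trend removed and 0.224 with estimated counts. Of 11 measured genes of the mast cell, basophil and eosinophil list, 7 rose and 0 fell (9 and 0 adjusted over the list alone; median 1.09; camera adjusted p = 4.6e-09; adjusted p = 0.521 with an estimated correlation). The eosinophil ribonuclease genes Ear6 (1.31 ± 0.24) and Ear2 (1.07 ± 0.19) and Gata2, a transcription factor of early and mast cell progenitors (0.86 ± 0.15), rose as well, but with all 14 libraries in 1 fit their adjusted p-values were 0.0701, 0.0701 and 0.111, and that of Ear6 was 0.181 with estimated counts. Of 19 monocyte genes, 9 rose and 0 fell (14 and 0 adjusted over the list alone; median 0.36; camera adjusted p = 2.4e-07; adjusted p = 0.521 with an estimated correlation). Among them were lysozyme, Lyz2 (0.58 ± 0.10, adjusted p = 0.000669, but 0.692 with all 14 libraries in 1 fit), and Ly86, the partner of the TLR4-like receptor CD180 (0.67 ± 0.15, adjusted p = 0.0072, but 0.235 without GMP_Plas replicate 2). The primary granule list, which marks neutrophil-committed GMP, had negative changes in 16 of 16 genes (median -0.44), and 10 fell while 0 rose (11 and 0 adjusted over the list alone; camera adjusted p = 4.3e-07; adjusted p = 0.521 with an estimated correlation). Gfi1, a repressor needed for neutrophil fate, fell by 0.69 ± 0.10 (adjusted p = 4.7e-05, but 0.0991 with estimated counts and 0.120 with all 14 libraries in 1 fit). Prtn3, proteinase 3, fell by 0.49 ± 0.10 (adjusted p = 0.00439, but 0.0746 without GMP_PBS replicate 1 and 0.134 without GMP_Plas replicate 2). The granule enzymes Mpo (-0.17 ± 0.11, adjusted p = 0.478) and Elane (-0.14 ± 0.10, adjusted p = 0.540) were not past the test.

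Among the other genes that fell in GMP were Lrg1, an acute-phase glycoprotein of granulocytes (-1.45 ± 0.20, adjusted p = 4.7e-05), S100a11, a calcium-binding protein (-1.13 ± 0.13, adjusted p = 8.4e-07), and Ndufa4, a subunit of cytochrome c oxidase (-1.30 ± 0.17, adjusted p = 0.000175, but 0.0595 with estimated counts). The inducible heat-shock genes Hspa1a (-1.14 ± 0.13) and Hspa1b (-1.07 ± 0.11) fell, though they are near-identical copies and their split of reads is uncertain. Slc40a1, the iron exporter ferroportin, fell by 0.92 ± 0.14 (adjusted p = 0.000167), Txn1, thioredoxin, fell by 0.88 ± 0.12 (adjusted p = 6.6e-05, but 0.0555 with all 14 libraries in 1 fit), and Tfrc, the transferrin receptor, rose by 0.57 ± 0.09 (adjusted p = 0.000348, but 0.151 with all 14 libraries in 1 fit). Of 18 heme and iron genes 1 rose and 3 fell, and the list was not past camera (adjusted p = 0.181). The cholesterol synthesis list moved down (24 genes, 0 up and 1 down, 0 and 3 adjusted over the list alone; median -0.25; camera adjusted p = 0.000179; adjusted p = 0.521 with an estimated correlation). Mature neutrophil genes did so too (17 genes, 0 up and 1 down, 0 and 4 adjusted over the list alone; camera adjusted p = 0.00524; adjusted p = 0.61 with an estimated correlation), but not without GMP_PBS replicate 2 (0.455) or GMP_Plas replicate 2 (0.0567). The lists for glucocorticoid response (0.0224), glycolysis (0.0269) and G2/M (0.0366) had downward camera calls that each ended in at least 2 of the 4 fits with a library left out and at an estimated correlation (adjusted p = 0.521, 0.54 and 0.54 with an estimated correlation). Without GMP_PBS replicate 2 they stood at 0.0533, 0.0853 and 0.213, without GMP_Plas replicate 1 the first and the last at 0.0634 and 0.269, and glycolysis at 0.0670 without GMP_PBS replicate 1 and 0.189 without GMP_Plas replicate 2. Lists for NF-kB (adjusted p = 0.288), toll-like receptor (0.564), chromatin modifier (0.288) and tolerance (0.115) genes were not past camera, with 0 genes past the edgeR test in each.

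**Figure D2:**
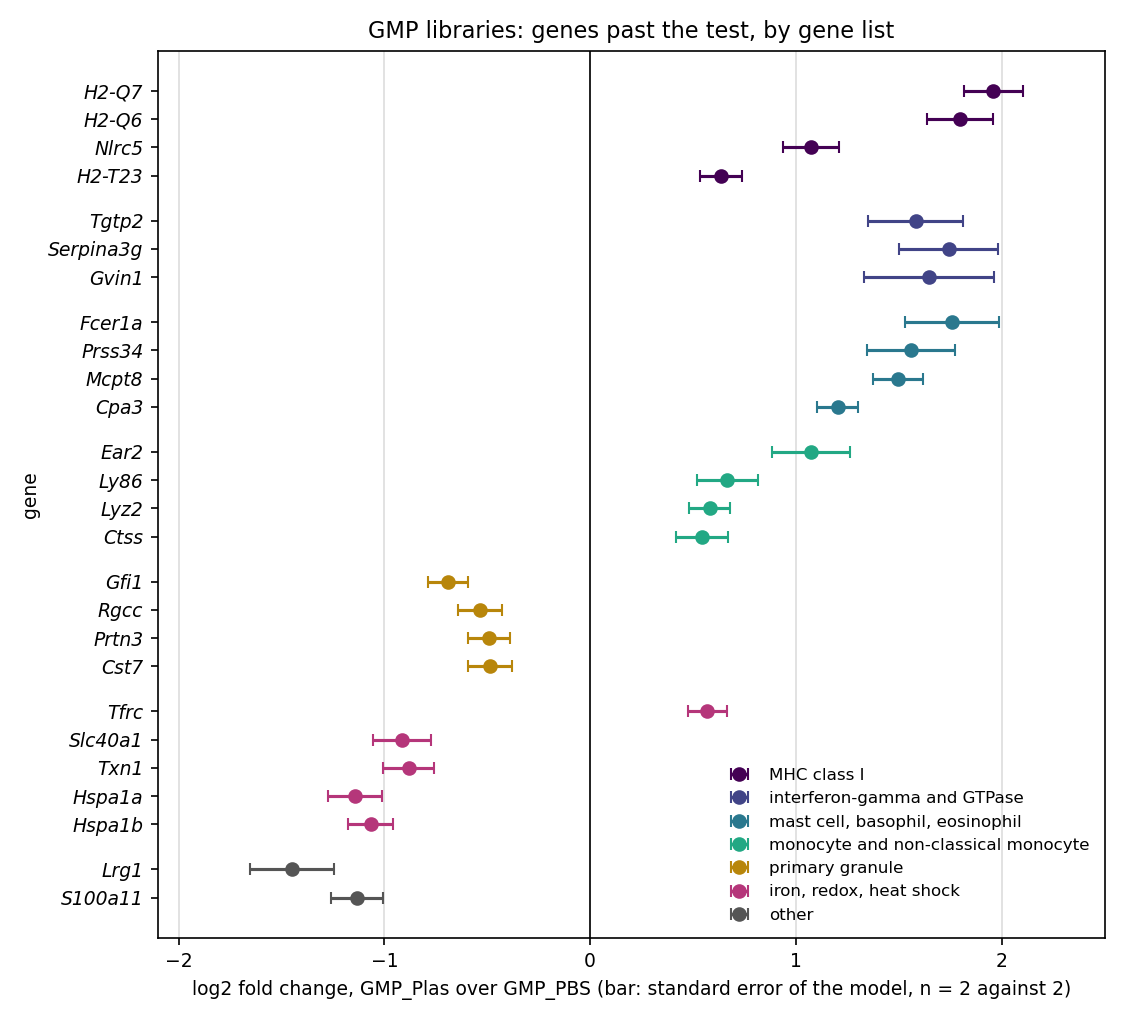
Log2 fold change of Plas over PBS in GMP for 26 genes grouped by list, with bars for the SE (n = 2 libraries per group). H2-Q7 (1.96) and Fcer1a (1.76) lie far above 0, and Lrg1 (-1.45) and Gfi1 (-0.69) below it.

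In monocytes without CLP, the transcripts that rose after infection were those of IgG heavy chains. Ighg2c, the constant region of IgG2c, rose by 4.07 ± 0.30 on the log2 scale (SE, n = 2 per group, adjusted p = 1.3e-05), with 823 and 885 CPM in the Plas libraries against 40.8 and 61.4 in PBS. Ighg1 rose by 3.75 ± 0.46 (adjusted p = 0.00343) and Ighg2b by 2.29 ± 0.32 (adjusted p = 0.00966); the constant regions share sequence, so the split of reads among them is uncertain. The Ighg1 call ended without monocyte PBS replicate 2 (0.309) and with estimated counts (0.0527). That of Ighg2b ended without PBS replicate 1 (0.628) or PBS replicate 2 (0.770), with estimated counts (0.0527) and with limma-trend (0.0554). These 3 genes of 5568 were past the edgeR test, and the count was 1 without PBS replicate 2 and 6 without either Plas_CLP library. Of 8 plasma cell genes 3 rose and 0 fell (6 rose adjusted over the list alone; median 1.99; camera adjusted p = 8.0e-09; adjusted p = 0.167 with an estimated correlation; fry adjusted p = 0.0256). The light chain Igkc (1.68 ± 0.34, adjusted p = 0.311) was not past the test.

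Interferon genes had small positive changes in the monocytes of infected mice. In the type I list, 29 of 30 were positive (median 0.52), 0 were past the test over all genes and 3 adjusted over the list alone (camera adjusted p = 6.9e-08; adjusted p = 0.331 with an estimated correlation). Oas3, an antiviral RNA synthetase (1.18 ± 0.32), and H2-Q7 (1.73 ± 0.48) were among the genes not past the test. Of 11 interferon-gamma GTPase genes 0 were past it and 4 adjusted over the list alone (median 0.72; camera adjusted p = 5.2e-05; adjusted p = 0.167 with an estimated correlation). The MHC class I list moved up without a single gene past the test (19 genes, median 0.45; camera adjusted p = 0.000357; adjusted p = 0.985 with an estimated correlation), and not without PBS replicate 2 (0.0584). At this depth 23.8% of simulated 2-fold changes and 90.8% of simulated 4-fold changes were detected, so most smaller shifts of single genes were not detectable. B-cell genes measured in this fit showed little change, Ighm at -0.11, Cd79a at -0.21 and Cd79b at 0.11.

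**Figure D3:**
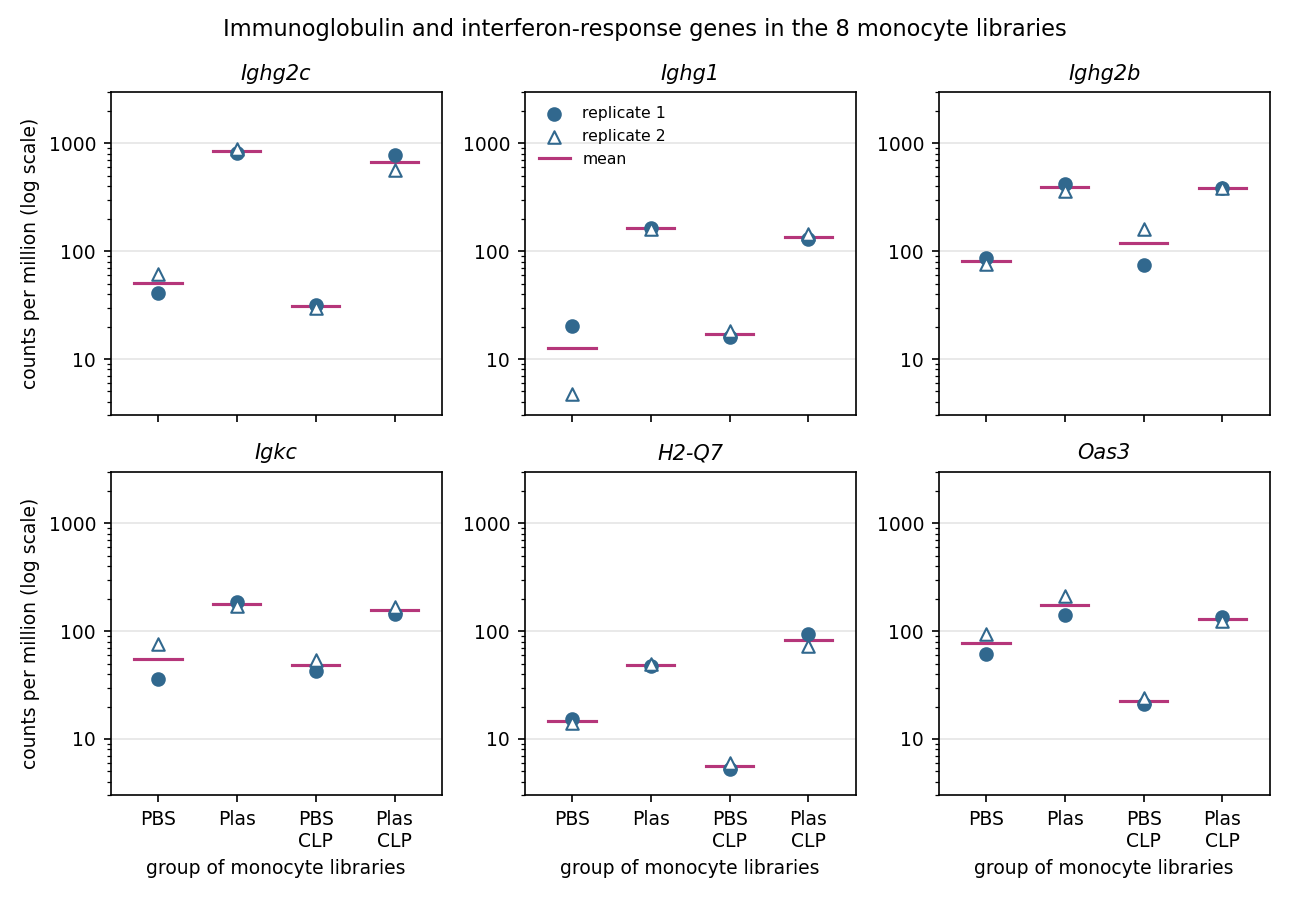
CPM on a log axis of Ighg2c, Ighg1, Ighg2b, Igkc, H2-Q7 and Oas3 in each of the 8 monocyte libraries by group, with group means. Ighg2c is at 823 and 885 CPM in the Plas libraries and at 40.8 and 61.4 in PBS.

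In monocytes of PBS mice, genes of the IL-6, STAT3 and acute-phase list had risen 3 hours after CLP, among them Socs3 and Pim1. Socs3, the inhibitor of cytokine signalling through STAT3, had 105 counts against 0 and was at least 40.7-fold higher (adjusted p = 0.000778, but 0.0580 without monocyte PBS replicate 2). Pim1, a STAT-induced survival kinase, rose by 3.69 ± 0.39 on the log2 scale (SE, n = 2 per group, adjusted p = 0.00036). Nfkbia, the NF-kB inhibitor IkBa, rose by 2.91 ± 0.29 (adjusted p = 0.00031), and Sbno2, a corepressor downstream of IL-10, by 2.60 ± 0.26 (adjusted p = 0.00031). Bcl3, a nuclear IkB protein, rose by 2.89 ± 0.34, Junb, an AP-1 subunit, by 2.57 ± 0.31, and Ccr1, a chemokine receptor, by 2.45 ± 0.30; without PBS replicate 2 their adjusted p-values were 0.0660, 0.0760 and 0.0770. Il1r2, the IL-1 decoy receptor, had 33 counts against 2, a ratio of 19.2 with a counting interval of 4.90 to 165 (adjusted p = 0.0143, but 0.195 without PBS replicate 1, 0.0760 without PBS replicate 2 and 0.208 without PBS_CLP replicate 2). Txnip, a glucose-sensitive inhibitor of thioredoxin, fell by 2.40 ± 0.28 (adjusted p = 0.000778). Pim1, Nfkbia, Sbno2 and Txnip stayed past the test in all 19 alternatives. Zfp36l2, an mRNA decay factor, fell by 1.99 ± 0.32 (adjusted p = 0.00922, but 0.179 without PBS replicate 1, 0.0953 without PBS replicate 2 and 0.301 without PBS_CLP replicate 2). A total of 34 of 5568 genes changed, 28 up and 6 down (82.4% up, against 58.7% with only the 4 libraries compared). The count depended on single libraries: 8 without PBS replicate 1, 5 without PBS replicate 2, 9 without PBS_CLP replicate 2, 217 (54.8% up) without Plas_CLP replicate 1 and 216 (53.7% up) without Plas_CLP replicate 2.

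Of 19 NF-kB genes, 2 rose and 0 fell after CLP in PBS mice (13 rose adjusted over the list alone; median 1.87, or 1.85 with genes near 0 counts at their bound; camera adjusted p = 9.8e-12; adjusted p = 0.621 with an estimated correlation). Of 14 genes of the IL-6, STAT3 and acute-phase list, 6 rose and 0 fell (10 rose adjusted over the list alone; median 1.67; camera adjusted p = 8.1e-10; adjusted p = 0.621 with an estimated correlation). Of 15 immediate-early genes, 2 rose and 0 fell (9 and 1 adjusted over the list alone; median 1.68; camera adjusted p = 7.5e-05; adjusted p = 0.621 with an estimated correlation). Type I interferon genes moved the other way, with negative changes in 25 of 30 (median -0.51; camera adjusted p = 0.000207; adjusted p = 0.621 with an estimated correlation) and 0 past the gene test. The glucocorticoid list of 8 genes, 1 of them up, was past camera (adjusted p = 0.0419; adjusted p = 0.621 with an estimated correlation), a call that ended without PBS replicate 1 (0.167), PBS_CLP replicate 1 (0.0547), PBS_CLP replicate 2 (0.145), Plas_CLP replicate 1 (0.0643) or Plas_CLP replicate 2 (0.0576).

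In mice infected before, CLP raised the same kinds of genes. Socs3 rose by 7.08 ± 0.42 on the log2 scale (SE, n = 2 per group, adjusted p = 9.6e-07), Pim1 by 3.93 ± 0.25 (adjusted p = 9.6e-07), Bcl3 by 3.91 ± 0.26 (adjusted p = 9.6e-07) and Il1r2 by 3.32 ± 0.28 (adjusted p = 1.4e-05). The acute-phase gene Saa3 rose by 6.50 ± 0.77, the phosphatase gene Dusp1 by 5.35 ± 0.66 and the cytokine gene Il1b by 3.99 ± 0.47, each at adjusted p = 0.000312, but with limma-trend they stood at 0.998, 0.139 and 0.830, and Il1r2 at 0.281. Icam1, an adhesion molecule, rose by 2.69 ± 0.29 (adjusted p = 0.000109), Tlr2, the receptor for bacterial lipopeptides, by 2.56 ± 0.30 (adjusted p = 0.000168), Kdm6b, a histone demethylase, by 2.31 ± 0.34 (adjusted p = 0.00124), and Cebpb, a transcription factor of emergency myelopoiesis, by 1.93 ± 0.25 (adjusted p = 0.0004). Cx3cr1, the fractalkine receptor, fell by 1.73 ± 0.33 (adjusted p = 0.0097, but 0.0801 without Plas replicate 1 and 0.184 without Plas replicate 2), and Zeb2, a monocyte lineage factor, fell by 1.39 ± 0.26 (adjusted p = 0.0094, but 0.0694 and 0.0783 without the same libraries). Txnip fell by 1.16 ± 0.22 (adjusted p = 0.0094). Of the 35 genes named by the rule, 10 were past the test in all 20 alternatives: Socs3, Pim1, Bcl3, Sema6b, Junb, Tlr2, Icam1, Ccr1, Cebpb and Kdm6b. A total of 136 genes changed, 115 up and 21 down. That count was 40 without Plas replicate 1, 49 without Plas replicate 2, 909 (53.6% up) without Plas_CLP replicate 1 and 558 (57.0% up) without Plas_CLP replicate 2.

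In these mice 13 of 19 NF-kB genes rose and 0 fell after CLP (17 rose adjusted over the list alone; median 1.70; camera adjusted p = 2.3e-25; adjusted p = 0.219 with an estimated correlation). In the IL-6, STAT3 and acute-phase list 9 of 14 rose and 0 fell (12 rose adjusted over the list alone; median 1.57; camera adjusted p = 7.4e-22; adjusted p = 0.219 with an estimated correlation), and in the immediate-early list 7 of 15 rose and 0 fell (10 and 1 adjusted over the list alone; camera adjusted p = 1.2e-09; adjusted p = 0.296 with an estimated correlation). Of 28 toll-like receptor and inflammasome genes 6 rose and 0 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.00141; adjusted p = 0.219 with an estimated correlation), among them Cd14, the LPS co-receptor (2.40 ± 0.34, adjusted p = 0.00111, but 0.110 with limma-trend and 0.111 after thinning). Of 11 genes of the tolerance and negative regulator list, 5 rose and 0 fell (5 and 0 adjusted over the list alone). Its camera adjusted p was 6.3e-06, or 0.262 with an estimated correlation. Among them was Tnfaip3, the ubiquitin editor A20 (2.73 ± 0.40, adjusted p = 0.00134, but 0.0595 with limma-trend). Lists share genes, and Tnfaip3 is also in the NF-kB list, so these calls are not separate results. Heat-shock genes moved down (7 genes, 0 up and 1 down, 0 and 5 adjusted over the list alone; median -0.66; camera adjusted p = 0.000181; adjusted p = 0.354 with an estimated correlation), with Hsph1, a co-chaperone, at -2.19 ± 0.38 (adjusted p = 0.00528, but 0.0750 without Plas replicate 1 and 0.0552 without Plas replicate 2). Upward camera calls for the glucocorticoid (0.00623) and myeloid factor lists (0.0104) ended without Plas_CLP replicate 2 (0.172 and 0.127). Downward calls for the type I interferon (0.00235) and monocyte lists (0.0216) ended without Plas_CLP replicate 1 (0.448 and 0.478) or Plas replicate 2 (0.0762 and 0.0643), and that for mitochondrial genes (4.1e-05) without Plas_CLP replicate 1 (0.921). The call for neutrophil genes (0.0172, down) ended without PBS replicate 1 (0.0792), PBS replicate 2 (0.0803), Plas replicate 1 (0.372) or Plas_CLP replicate 1 (0.408). In the same order these 6 lists stood at adjusted p = 0.354, 0.262, 0.413, 0.437, 0.571 and 0.559 with an estimated correlation.

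Of the 28 genes that CLP raised in PBS mice and the 115 it raised in Plas mice, 24 were the same, against 0.578 by chance (Fisher's exact test, p = 5.5e-38). That p treats genes as independent, and both comparisons came from 1 fit. Txnip was the 1 gene lower in both, and 0 genes went in opposite directions. Across all 5568 genes the fold changes correlated at r = 0.509, where genes are not independent replicates. Hif1a, the hypoxia-response factor, rose by 2.06 ± 0.32 in PBS mice (adjusted p = 0.00716, but 0.0857 without PBS replicate 1, 0.193 without PBS replicate 2 and 0.109 without PBS_CLP replicate 2) and was at 0.65 ± 0.23 in Plas mice (adjusted p = 0.190). Its difference between the arms was not past the test (-1.41 ± 0.40, adjusted p = 0.811).

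**Figure D4:**
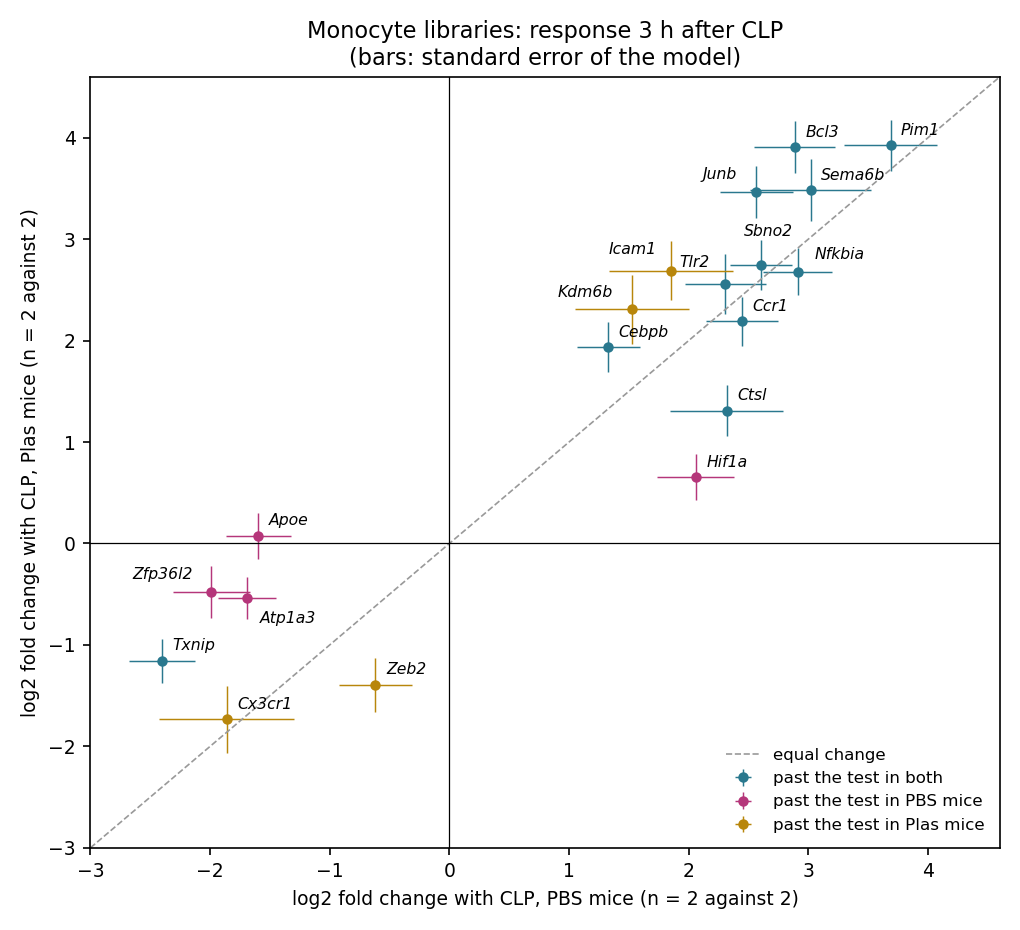
Log2 fold change of CLP over no CLP for 19 genes in monocytes of PBS mice (x axis) and Plas mice (y axis), with bars for the SE, coloured by the arm in which the gene was past the test. Pim1 (3.69 and 3.93) and Txnip (-2.40 and -1.16) were past it in both.

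Among monocytes of mice with CLP, 3 genes were higher after earlier infection, Ighg2c, Ighg1 and H2-Q7, and only Ighg2c was past the test in all alternatives. Ighg2c rose by 4.40 ± 0.34 on the log2 scale (SE, n = 2 per group, adjusted p = 2.3e-05). H2-Q7 had 635 counts in Plas_CLP against 2 in PBS_CLP, a ratio of 13.2 with a counting interval of 3.64 to 109 (adjusted p = 0.0477), and Ighg1 rose by 3.02 ± 0.46 (adjusted p = 0.0411). These were the 3 genes past the test, and H2-Q7 stayed past it in 5 of 19 alternatives. Both H2-Q7 and Ighg1 were lost in several fits with 1 library left out. For Ighg1 these were PBS replicate 1 (0.0561), PBS replicate 2 (0.0600), Plas replicate 1 (0.0591), PBS_CLP replicate 1 (0.757) and PBS_CLP replicate 2 (0.704), and for H2-Q7 the same libraries (0.147, 0.146, 0.0711, 0.757 and 0.704) and Plas replicate 2 (0.0654). The count was 1 when any of the 5 libraries named for Ighg1 was left out, 2 without Plas replicate 2, 64 (51 up and 13 down) without Plas_CLP replicate 1 and 238 (108 up and 130 down) without Plas_CLP replicate 2. In the type I interferon list 29 of 30 genes were positive (median 0.92), 0 past the test over all genes and 13 adjusted over the list alone (camera adjusted p = 4.5e-10; adjusted p = 0.318 with an estimated correlation). Oas3 was at 2.49 ± 0.45 (adjusted p = 0.108). Of 19 MHC class I genes 1 rose (8 adjusted over the list alone; median 0.90; camera adjusted p = 1.9e-08; adjusted p = 0.521 with an estimated correlation). Of 8 plasma cell genes 2 rose (5 and 1 down adjusted over the list alone; median 1.71; camera adjusted p = 3.5e-05; adjusted p = 0.318 with an estimated correlation). Ighg1 and Ighg2c were the 2 genes also past the test in mice without CLP (chance 0.00162, Fisher's exact test, p = 5.8e-07). That p treats the calls as independent, although the 2 genes share sequence and both comparisons came from 1 fit. Across all 5568 genes the infection effects with and without CLP correlated at r = -0.0227 and had the same sign in 45.9%. Camera calls for MHC class II (0.00752) and interferon-gamma GTPase genes (0.0337) upward ended without PBS_CLP replicate 1 (0.217 and 0.331) or Plas_CLP replicate 2 (0.268 and 0.312). Those for mitochondrial (4.7e-06) and S-phase genes (0.0337) downward ended without Plas_CLP replicate 1 (0.352 for both), the latter also without PBS_CLP replicate 2 (0.292). With an estimated correlation these 4 lists stood at adjusted p = 0.564, 0.521, 0.689 and 0.689.

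Whether the CLP response differed after infection was tested as an interaction, and 0 of 5568 genes were past edgeR's test, 0 by DESeq2 and 0 by limma-trend, with 338 at an unadjusted p under 0.05 against 278 by chance. The genes with the smallest p included Apoe, a lipid carrier of macrophages (1.67 ± 0.35), and Ppp1r9b, a cytoskeletal scaffold (1.79 ± 0.39), both at adjusted p = 0.811. The count was 39 without Plas_CLP replicate 1 and 105 without Plas_CLP replicate 2. On simulated data 47.7% of 4-fold differences were detected. Type I interferon genes (median 0.35, camera adjusted p = 0.185) and NF-kB genes (median 0.13 but mean -0.54, adjusted p = 0.856) were not past camera. MHC class I genes, positive in 15 of 19 (median 0.54), were past it (adjusted p = 0.0467; adjusted p = 0.951 with an estimated correlation), but not without PBS replicate 1 (0.566), PBS_CLP replicate 1 (0.544), Plas replicate 1 (0.141) or Plas_CLP replicate 2 (0.376). Mitochondrially encoded genes were negative in 12 of 12 (median -1.10, adjusted p = 9.5e-06; adjusted p = 0.951 with an estimated correlation).

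The effect of infection was compared between GMP and monocytes without CLP, and 0 of 11234 genes were past edgeR's test for a difference, 0 by DESeq2 and 1 by limma-trend, with 490 at an unadjusted p under 0.05 against 562 by chance. Apoe (1.46 ± 0.32, adjusted p = 0.512) and Lrg1 (-2.07 ± 0.52, adjusted p = 0.843) were among the genes with the smallest p. Without GMP_Plas replicate 1 or replicate 2 the count was 1, and without either Plas_CLP library it was 14. The 3 IgG genes past the test in monocytes were not measured in the GMP fit, so an overlap of calls could not arise. Genes of the monocyte list had the more positive change in GMP (15 of 19, median 0.41; camera adjusted p = 3.8e-05; adjusted p = 0.273 with an estimated correlation).

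Between GMP and monocytes of PBS mice, granule genes stood against mature myeloid genes. Mpo, myeloperoxidase, was higher in GMP by 3.11 ± 0.23 on the log2 scale (SE, n = 2 per group, adjusted p = 7.5e-12), Ctsg, cathepsin G, by 2.56 ± 0.25, Kit by 2.62 ± 0.33 and Cd34 by 3.12 ± 0.39. Epx, eosinophil peroxidase, had 4178 counts against 0 and was at least 30.3-fold higher. Vcan, the matrix proteoglycan versican (-8.53), Lyz2 (-5.99 ± 0.27) and Ctss, cathepsin S (-5.08 ± 0.25), were lower in GMP. Of 16 primary granule genes 15 were higher and 1 lower (adjusted p = 0.0989 with an estimated correlation), and of 19 monocyte genes 0 were higher and 16 lower (camera adjusted p = 3.1e-16, still past the test at adjusted p = 0.0128 with an estimated correlation). Of 45 type I interferon genes 36 were lower and 0 higher in GMP (39 lower adjusted over the list alone; adjusted p = 0.0298 with an estimated correlation). Of 24 S-phase genes 13 and of 19 unfolded-protein genes 12 were higher and 0 lower, while of 24 G2/M genes 1 was higher and 2 lower (median -0.19, camera adjusted p = 0.0812). Of 19 mature neutrophil genes 13 were lower in GMP and 0 higher (adjusted p = 0.0798 with an estimated correlation), Mmp8 by 5.27 ± 0.33. B-cell genes were lower in GMP in 11 of 17 (median -6.24, or -4.94 with genes near 0 counts at their bound). In all, 973 genes were higher and 1178 lower of 11234, a total of 2151 that was 1210 without monocyte PBS replicate 1 and 1108 without PBS replicate 2. The balance turned with the method, to 1429 higher and 1060 lower with limma-trend and 711 higher and 1491 lower with DESeq2. With an estimated correlation 10 of 25 list calls held.

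The 2 libraries labelled HSPC (335393 and 326350 hits, 1 per condition and so compared without a test) held transcripts of mature blood cells and 0 counts of Kit, Cd34, Mpo and Elane. Arpc2, an actin-nucleating subunit, took 10.75% of hits in the PBS library (95% Wilson interval 10.64 to 10.85) and 8.04% in the Plas library (7.95 to 8.13). The globin gene Hba-a1 was at 15890 and 14090 CPM, against at most 0.406 CPM in GMP, and Retnlg, a neutrophil resistin, at 4207 and 7924 CPM, against 0 in GMP. Cd79a, a B-cell receptor chain, was at 3742 and 1786 CPM. The PBS library detected 2381 genes and the Plas library 3406. In the Plas library 1324 genes were at least 2-fold higher and 704 lower of 2868 with at least 20 CPM. Mmp8, a neutrophil collagenase, had 629 counts against 0, at least 197-fold higher by counting error alone. Hspa8, a chaperone, had 506 against 2 (log2 ratio 6.92, counting interval 6.03 to 10.94). With few genes detected and no molecular identifiers, these bounds may be too large, as may those of the next genes. Thrap3, a splicing factor, was at least 36.6-fold lower, and Decr1, a fatty acid oxidation enzyme, lower (log2 ratio -5.21, interval -9.27 to -4.33). Type I interferon genes were higher in the Plas library in 19 of 20 (median log2 ratio 3.22, percentile 100 among random lists), and interferon-gamma GTPase genes in 9 of 9 (median 2.67, percentile 96.0). Genes of the IL-6, STAT3 and acute-phase list were higher in 12 of 14 (median 2.98, percentile 99.9). Mature neutrophil genes had a median of 1.15 (percentile 98.7), and MHC class II genes were higher in 0 of 9 (median -0.83, percentile 6.49). Mitochondrially encoded genes were higher in 1 of 10 (median -1.60, percentile 0.14), and their share of hits was 2.10% in the PBS library (95% Wilson interval 2.05 to 2.15) against 0.89% in the Plas library (0.859 to 0.923).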

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

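All explanations weighed in this part were tested after the results had been seen, as was camera on z-scores, whereas the list tests for differences between groups were planned.

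Camera found 5 lists in which the effect of infection or CLP differed between groups, each by a test of the difference itself. In the monocyte interaction, the change with CLP was more positive after infection for MHC class I genes (median log2 difference 0.54, 15 of 19 genes positive, adjusted p = 0.0467; adjusted p = 0.951 with an estimated correlation). It was more negative for mitochondrially encoded genes (median -1.10, 12 of 12 negative, adjusted p = 9.5e-06; adjusted p = 0.951 with an estimated correlation). With each library left out in turn the MHC class I call held in 4 of 8 fits (adjusted p from 0.00328 to 0.566) and the mitochondrial call in 8 of 8. The 2 Plas_CLP libraries differed in the share of mitochondrially encoded transcripts, 2.46% in replicate 1 (95% Wilson interval 2.40 to 2.51) and 5.73% in replicate 2 (5.71 to 5.74). Between cell types without CLP, infection shifted the monocyte list further up in GMP (15 of 19 genes, adjusted p = 3.8e-05; adjusted p = 0.273 with an estimated correlation). The plasma cell list was shifted further up in monocytes (adjusted p = 1.9e-07; adjusted p = 0.0606 with an estimated correlation), as was the T and NK cell list (adjusted p = 1.1e-08; still past the test at adjusted p = 0.0276 with an estimated correlation). Each of these 3 held in 12 of 12 fits with a library left out. With camera on z-scores the plasma cell call was lost (adjusted p = 0.946), and the other 4 lists were past the test, with adjusted p of at most 0.0454. However, 13 of 18 T and NK cell genes were at 0 counts in both monocyte PBS libraries, and 2 in both GMP PBS libraries. Of 13 plasma cell genes 4 were at 0 in the former, 9 in the latter and 12 in either. Their fitted changes depend on the prior count, while 0 of the 19 monocyte genes were at 0. Shallow monocyte PBS libraries were set against deep monocyte Plas libraries in every fit with a library left out. Those fits therefore do not test depth as the source of these shifts.

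The IgG heavy chain transcripts in monocytes of infected mice were weighed against depth, B cells and plasma cells, and a change within the monocytes themselves was not tested. The number of hits as such is argued against for mice without CLP. With all 8 monocyte libraries thinned to 1 depth, Ighg2c, Ighg1 and Ighg2b were past the test there in 20 of 20 draws. Thinning evens the counts only. Both PBS libraries were shallow and both Plas libraries deep, so other differences that went with depth cannot be told apart from infection. With CLP the number of hits is argued against for Ighg2c alone (20 of 20). Ighg1 was past the test in 8 of those draws and Ighg2b, not past it at full depth either, in 7. Their log2 fold changes kept medians of 2.81 (2.47 to 3.42 over draws) and 1.63 (1.38 to 1.74), so the lost calls alone do not point to depth. A larger share of B cells as a whole is argued against too. B-cell list counts without Ighm, pooled over libraries, were 1.23 times as high in infected mice, far below the fold of Ighg2c. The upper bound of 1.44 covers counting error only, and single libraries held 168 to 284 CPM in PBS mice and 215 to 320 in infected mice. The list was not built for B cells that make IgG, so a rise in those alone was not tested. IgG plasma cells or their RNA among the sorted cells remain a candidate explanation, since the light chain Igkc had a mean infection effect of 1.70 ± 0.25 over both CLP states (adjusted p = 0.0117). Igkc was at 187 and 170 CPM in the Plas libraries where Ighg2c was at 823 and 885, but CPM are not scaled by gene length. Jchain (55.3 and 60.1 CPM against 20.4 and 0 in PBS) was not past the test, and Xbp1, which monocytes also express, was at -0.07. Whether the gate on CD11b and Ly6C removes plasma cells was not tested, and B-cell list transcripts without Ighm were at 168 to 320 CPM in the monocyte libraries. None of these values decides for or against plasma cells.

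The larger number of genes past the CLP test in Plas mice (136) than in PBS mice (34) was weighed against depth, 1 shallow library and a larger response. Depth may account for it, since after thinning to 1 depth the median ratio of calls was 0.820, with fewer calls in Plas mice in 17 of 20 draws. Whether the shallow Plas_CLP replicate 1 accounts for it could not be judged. Without it the ratio was 4.19, but that fit kept 1 library in its group and set deep Plas libraries against shallow PBS ones. The counts also moved when other single libraries were left out. A larger response after infection cannot be told apart from no difference here, since NF-kB genes had an adjusted p of 0.856 in the interaction, whose test detected 47.7% of simulated 4-fold differences.

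The libraries labelled HSPC lacked Kit and Cd34, the markers of their gate. Few distinct molecules may be part of the reason, since the richer of the 2 libraries held 35.1% as many detected genes as the poorest GMP library thinned to the same total. RNA of mature blood cells was in both libraries, although the lineage-negative gate should remove such cells. Of 6 marker genes, 5 (Hba-a1, Hba-a2, Cd79a, Igkc and Retnlg) were at least 10 times higher in both libraries than in any GMP library. S100a9 was not (2800 and 5966 CPM against 477). Whether mature blood cells or their RNA account for the missing Kit and Cd34 remains open. A wrong label was not tested, and the design gives no biological explanation to test.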

How the results depend on the processing

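The thinned, length-trend, crossed-pairing and z-score tests were chosen after the results were seen, and the others were planned. For 131 named gene results, 2283 comparisons with an alternative kept the call in 1931, lost it in 352 and reversed it in 0; 42 results were past the test in every alternative run. Below, counts of genes past the test are given where they moved by more than 1.5 times, and the cause was not tested unless stated. For GMP Plas vs PBS (363) the count was 74 with estimated counts, 181 with DESeq2, 42 with all 14 libraries in 1 fit and 17 against a 1.5-fold change, the last by construction as in each comparison below. For monocyte Plas vs PBS (3) it was 5 without a filter and 19 with only the 4 libraries compared. For CLP in PBS mice (34) it was 10 with estimated counts, 77 with DESeq2, 78 with limma-trend, 93 without a filter, 61 with all 14 libraries, 17 against a 1.5-fold change, 155 with only the 4 libraries and 52 in the first thinned draw (median 57 over 20 draws). For CLP in Plas mice (136) it was 56 with estimated counts, 25 with limma-trend, 350 without a filter, 802 with all 14 libraries, 62 against a 1.5-fold change, 233 with crossed replicate numbers and 53 in the first thinned draw (median 50 over 20 draws). For Plas_CLP vs PBS_CLP (3) it was 1 with estimated counts, 5 with DESeq2, 22 without a filter, 5 with the filter of 50 counts, 15 with all 14 libraries, 1 against a 1.5-fold change and 1 with only the 4 libraries. The interaction (0) had 2 without a filter, the difference between cell types (0) had 1 with limma-trend and 14 without a filter, and GMP vs monocyte PBS (2151) had 1242 against a 1.5-fold change.

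Leaving out 1 library gave 155 to 618 genes for GMP Plas vs PBS, 1 to 6 for monocyte Plas vs PBS, 5 to 217 for CLP in PBS mice, 40 to 909 for CLP in Plas mice, 1 to 238 for Plas_CLP vs PBS_CLP, 0 to 105 for the interaction, 0 to 14 for the difference between cell types and 1108 to 2718 for GMP vs monocyte PBS. The lone library left in a group was assumed to vary like the others. For the CLP comparisons the counts rose when a Plas_CLP library was left out, and the cause was not tested. With the replicate number as a block the counts were 311, 3, 38, 114, 2, 0, 0 and 1795 in the same order, but residual correlations of the pairing ranged from -0.476 to 0.07 in monocytes, so the numbers were not taken as pairs. The share of calls that were upward also moved: in GMP from 43.5% to 66.7% with all 14 libraries, for CLP in Plas mice from 84.6% to 60.7% with all 14 libraries and 53.6% without Plas_CLP replicate 1, for CLP in PBS mice from 82.4% to 53.7% and for Plas_CLP vs PBS_CLP from 100% to 45.4%, both without Plas_CLP replicate 2. For GMP vs monocyte PBS it went from 45.2% to 57.4% with limma-trend and 32.3% with DESeq2. The fit of all 14 libraries moved the median of all genes by 0.134 in monocyte Plas vs PBS and by 0.13 in Plas_CLP vs PBS_CLP.

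For the list tests, an estimated correlation left 0 calls of 12 in GMP, 0 of 4 in monocyte Plas vs PBS, 0 of 5 and 0 of 13 for CLP in PBS and Plas mice, 0 of 7 in Plas_CLP vs PBS_CLP, 0 of 2 in the interaction, 1 of 3 for the difference between cell types and 10 of 25 for GMP vs monocyte PBS. Fry gave 1, 1, 3, 5, 0 and 0 for the first 6. Camera on z-scores gave 8 for CLP in PBS mice and 5 for the difference between cell types. Leaving out 1 library gave 4 to 8 lists for CLP in PBS mice and 1 to 4 for the interaction. Lists whose median, mean and camera direction differed in sign numbered 1 to 16 per comparison, and 0 of them were past camera. The overlap of Plas effects with and without CLP (2) was 1 at an adjusted p of 0.01, and that of the CLP responses (25) was 12 at 0.01 and 41 at 0.10, by construction of the threshold. In the libraries labelled HSPC, 2028 genes differed by at least 2-fold, and 1510 to 2060 did so in the alternatives. Depth limited the 5 shallow monocyte libraries to a floor of 9.21 to 18.0 CPM, and 73.3% of simulated 4-fold changes were detected for CLP in PBS mice against 98.5% in GMP.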

Other observations

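The tests in this part were all chosen after the results had been seen. Averaged over monocytes with and without CLP, 7 genes rose after infection and 0 fell (edgeR). Besides Ighg2c (4.23 ± 0.23), Ighg1 and Ighg2b, these were H2-Q7 (2.76 ± 0.40, adjusted p = 0.00922), Igkc (1.70 ± 0.25), Oas3 (1.84 ± 0.28, adjusted p = 0.0122) and Oasl2, an antiviral synthetase-like protein (2.35 ± 0.40, adjusted p = 0.0327). Type I interferon genes were positive in 30 of 30 (median 0.67), with 2 up over all genes and 19 adjusted over the list alone (camera adjusted p = 5.8e-17; adjusted p = 0.0946 with an estimated correlation). MHC class I genes were positive in 18 of 19 (median 0.53; camera adjusted p = 2.6e-11; adjusted p = 0.342 with an estimated correlation), and MHC class II genes in 6 of 6 (4 up adjusted over the list alone; camera adjusted p = 0.00164; adjusted p = 0.414 with an estimated correlation). In the same test mitochondrially encoded genes were negative in 12 of 12 (median -0.11, camera adjusted p = 0.0340, or 0.799 with an estimated correlation). That mean joins opposite effects of infection, with a median of 0.42 without CLP and -0.68 with CLP. The nonclassical monocyte list moved up (median 0.28, camera adjusted p = 0.0332, or 0.740 with an estimated correlation). Before averaging, the infection effects with and without CLP correlated at r = -0.0227 across 5568 genes.

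Averaged over PBS and Plas mice, CLP changed 223 genes in monocytes, 154 up and 69 down. Cdkn2d, a cyclin-dependent kinase inhibitor (2.36 ± 0.22), Myd88, the toll-like receptor adaptor (1.28 ± 0.21), Stat3, which relays IL-6 signals (1.20 ± 0.19), Il6st, the shared IL-6 receptor chain (1.10 ± 0.20), and Nfil3, a leucine zipper factor (1.83), rose. Samd9l, an interferon-induced growth inhibitor, fell by 1.46 ± 0.25, and 15 of 19 NF-kB genes rose. Type I interferon genes had a median of -0.39 with 2 of them lower (camera adjusted p = 2.3e-05; adjusted p = 0.385 with an estimated correlation). The monocyte list fell with them (4 of 19 positive, median -0.29; camera adjusted p = 0.0157; adjusted p = 0.423 with an estimated correlation), as did heat-shock genes (median -0.34; camera adjusted p = 0.0145; adjusted p = 0.524 with an estimated correlation).

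It was asked whether the genes changed in GMP by infection were shifted in monocytes too, in 3 tests of the mean infection effect. Of the 158 genes that rose in GMP, 113 were measured in monocytes, where their median was 0.0755 with 71 positive (camera adjusted p = 0.0146; adjusted p = 0.634 with an estimated correlation), so a shared shift stays open as a hypothesis. Without members of the interferon and MHC lists the median of the remaining 87 was 0.00193 with 45 positive (adjusted p = 0.632; 0.844 with an estimated correlation), and a shift beyond those lists may or may not exist. Of the 205 genes that fell in GMP, 140 were measured and had a median of 0.0589 with 85 positive (camera adjusted p = 0.632, and 0.844 with an estimated correlation). This set leaned upward, so the values gave no sign of a shared fall, without excluding one.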
